A study of Macaca fascicularis with 1862 samples.

How the data were processed

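The series profiled single cells of cynomolgus monkey (Macaca fascicularis) embryos that had been grown in culture from the blastocyst stage. Per the labels' protocols, oocytes were fertilised by sperm injection, blastocysts were taken into extended culture, extraembryonic tissue was cut away, and the inner embryonic bodies were dissociated with TrypLE. Single cells were then picked by hand under a microscope. Each cell went through scChaRM-seq, an assay that reads DNA methylation, chromatin accessibility and RNA from 1 cell. In this assay the enzyme M.CviPI, a GpC methyltransferase, marks open chromatin, oligo(dT) beads take the messenger RNA away, and the remaining genomic DNA is bisulfite converted and sequenced. Per the submitters' processing notes, Trim Galore 0.4.4, Bismark 0.7.6 and SAMtools 0.1.18 were used on the bisulfite reads. The genome build is not given in the sources used here.

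The table the authors deposited was the only file analysed here. It has 1 line per cell and 3 text columns: the identifier of the cell's RNA library, the identifier of its DNA library, and the cell type the authors gave it. It has 0 numeric columns, so methylation levels, accessibility, expression and read depth of the cells were not analysed here. How the authors assigned the cell types is not given in the sources used here. The types were taken as deposited and no cell was filtered out. Whether doublets were removed before deposit is not given either.

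All 1862 cells of the table matched 1 sample each through the DNA identifier, 0 were unmatched, and the type in the table equalled the type in the sample's title for 1862 of 1862 cells. The embryonic day was taken from the labels. The numbers of cells were 371 at E16, 128 at E18, 262 at E20, 138 at E21, 416 at E22, 262 at E23, 197 at E24 and 88 at E25, which makes 499 early and 1363 late cells as divided below. By type there were 376 EVT, 271 EXMC, 228 PS and derivative, 204 mesoderm, 198 CTB, 181 extraembryonic mesoderm, 121 non-neural ectoderm, 100 STB, 69 EPI, 58 neural ectoderm, 39 endoderm and 17 blood cells. The titles carry a number from 1 to 12 after the word embryo. Each number goes with 1 cell type, each type with 1 number, the same number stands before the type in the deposited table for 1862 cells, and all 12 numbers occur on more than 1 day. The number was therefore read as a code of the cell type and not as the name of an embryo. On that reading, which embryo, animal or culture a cell came from is not given in the sources used here. Cells of 1 embryo are not independent of each other, so each day was treated as 1 sample, and no test between days was made and no p-value is given. Shares of cells are given with exact (Clopper-Pearson) 95% binomial intervals. These cover counting error only, not differences between embryos, dissections or picking sessions. Where a type had no cell, the share that a count of 0 still allows was taken as 3 cells of the total. This is an approximation, rough for few cells, and differs from the upper bound of the exact interval.

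Before the deposited table was examined, the 12 types were put into 4 lineage classes by their names. The days were divided into early (E16 and E18) and late (E20 to E25). The types to describe were set as well: the leading type of each day, and the types whose early and late intervals do not overlap. The sample labels, which give the day and type of each cell, were already at hand, so these choices were not made blind. No gene is named because the table holds none. The trophoblast class holds CTB, EVT and STB, by their usual use the cytotrophoblast, extravillous trophoblast and syncytiotrophoblast of the placenta. The class of extraembryonic mesoderm and mesenchyme holds EXMC, by usual use extraembryonic mesenchyme, and the type named extraembryonic mesoderm. The embryonic class holds EPI (by usual use the epiblast), PS (by usual use the primitive streak) and derivative, mesoderm, neural ectoderm, non-neural ectoderm and endoderm. Blood cells form their own class.

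Technical units were read from the identifiers. The DNA libraries come from 21 batches, which the identifiers divide into a first series (batches 1 to 13, 1156 cells) and a second series (batches 14 to 21, 706 cells). RNA identifiers that differ only in the well number are called an RNA plate here. There are 44 such plates, each of 1 day, and the first part of the identifiers divides them into 7 sets. Batches and plates are technical units and not replicates, so their shares are given as ranges. Within-batch shares were computed for batches with at least 10 early and 10 late cells. For the 31 plates whose cells lie in both DNA series, the number of cells of each type in the second series was set against 10000 random divisions of the same cells within each plate, and again with the extraembryonic mesoderm and mesenchyme cells set aside, a choice made after the data had been seen. The division within plates was tried on simulated data, with fewer shuffles per run. In 20 runs with a random division, 0 fell below all shuffles. A random division rarely does so, and this count therefore measures no error rate. In 20 runs in which cells of 1 class were kept out of the second series by the toss of a coin, 20 did. Shuffles within runs of wells, or with a class set aside, were not tried in this way. Differences between late and early shares were set against their 95% Newcombe interval to judge alternatives. Alternatives covered equal weights for batches or plates, each batch, plate or day left out, other early and late days, types from the titles, each DNA series alone, and other cell minimums; weights by RNA plate, plates left out and days within 1 series were added after the data had been seen. Python 3.11.15, pandas 2.3.3, SciPy 1.17.1, NumPy 2.4.6 and matplotlib 3.10.9 were used.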

Results

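The data comprised single cells from cultured cynomolgus monkey embryos, each with a paired DNA and RNA library and a cell type given by the authors. The cells came from 8 embryonic days between E16 and E25. The most frequent type was EVT, an invasive trophoblast, with 20.2% of all cells (95% interval 18.4 to 22.1). EXMC made up 14.6% (12.98 to 16.2), PS and derivative, named for the streak through which gastrulating cells pass, 12.2% (10.8 to 13.8), mesoderm 10.96% (9.57 to 12.5), CTB 10.6% (9.27 to 12.1) and extraembryonic mesoderm 9.72% (8.41 to 11.2). Less frequent were non-neural ectoderm with 6.50%, STB with 5.37%, EPI with 3.71%, neural ectoderm with 3.11%, endoderm with 2.09% and blood cells with 0.913%. By class, 38.6% of cells were embryonic (36.4 to 40.9), 36.2% trophoblast (34.01 to 38.4) and 24.3% extraembryonic mesoderm and mesenchyme (22.3 to 26.3). These are shares of the cells that were profiled, after dissection and picking by hand, and each day counts as 1 sample.

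The first comparison asked which cell types were profiled on each day of culture, over a period that by the study's title reaches neurulation. At E16, PS and derivative cells led with 60.9% of cells (55.7 to 65.9), followed by EXMC with 26.95% (22.5 to 31.8). The lead came from 4 RNA plates whose cells were all in the first DNA series. In the 3 E16 plates with cells in both series EXMC led in each, with 67.6% against 14.8% PS and derivative in the first and 42.1% against 36.8% in the second. Of all PS and derivative cells, only 2 came from another day, 1 from E21 and 1 from E22. At E18 no cell was PS and derivative, which allows a share of up to 2.34%. E18 instead held 38.3% EVT (29.8 to 47.3), 15.6% mesoderm (9.81 to 23.1), and 12.5% each of EPI and endoderm (7.32 to 19.5). At E22 mesoderm led with 37.3% (32.6 to 42.1), followed by extraembryonic mesoderm with 26.9% (22.7 to 31.5). In the first series the order was the other way, with 33.4% mesoderm and 34.4% extraembryonic mesoderm, and in the second the shares were 49.5% and 3.03%.

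Neural ectoderm, the tissue that forms the neural tube, was seen almost only at E22, with 56 of its 58 cells. It made up 13.5% of E22 cells (10.3 to 17.1) and was present in 6 of 6 RNA plates of that day. Its other cells were 1 at E18 and 1 at E21. Non-neural ectoderm made up 11.3% of cells at E22 (8.42 to 14.7), with 8.20% in the first series and 21.2% in the second, and 25.95% at E23 (20.8 to 31.7), with 68 cells, where it was the leading type over all cells. At E23 it led in the second series, with 36.8%, while in the first it had 22 cells, behind EXMC with 37, EVT with 36 and CTB with 27. No neural ectoderm was seen at E23, E24 or E25, which allows up to 1.15%, 1.52% and 3.41% of all cells. Few of those cells were of the embryonic class. Among embryonic-class cells alone the absence allows up to 3.70% of 81 cells at E23, 60% of 5 at E24 and 14.3% of 21 at E25. The upper bounds of the exact intervals there are 4.45%, 52.2% and 16.1%. No non-neural ectoderm was seen at E16 or E18, which allows up to 0.809% and 2.34%.

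E20 and E24 were mostly trophoblast, the cells that form the outer layer of the embryo and the placenta. EVT led on both days, with 49.6% at E20 (43.4 to 55.8) and 48.2% at E24 (41.1 to 55.4), and it led in each DNA series on both days. With CTB and STB, the trophoblast class made up 81.3% of E20 cells (76.04 to 85.8) and 78.2% of E24 cells (71.7 to 83.7). The class was at 7.28% at E16 (4.85 to 10.4), 52.3% at E18 (43.3 to 61.2), 14.5% at E21 (9.08 to 21.5), 4.81% at E22 (2.96 to 7.33), 49.2% at E23 (43.03 to 55.5) and 50% at E25 (39.1 to 60.9). Over both DNA series together, the intervals of E20 and E24 overlap each other and not those of the remaining 6 days. In the first series alone E24, at 64.7% (55.4 to 73.2), overlapped E23, at 51.1% (42.4 to 59.7).

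The embryonic class was lowest on those same days, at 0.763% with 2 cells at E20 (0.0926 to 2.73) and 2.54% with 5 cells at E24 (0.829 to 5.82). It made up 64.96% of cells at E16 (59.9 to 69.8) and 64.2% at E22 (59.4 to 68.8). E18 was at 41.4% (32.8 to 50.4), E21 at 35.5% (27.6 to 44.1), E23 at 30.9% (25.4 to 36.9) and E25 at 23.9% (15.4 to 34.1). Extraembryonic mesoderm and mesenchyme was at 50% at E21 (41.4 to 58.6), where EXMC was the leading type with 43 cells or 31.2% (23.6 to 39.6). Of these, 42 were among the 88 first-series cells and 1 among the 50 second-series cells, where mesoderm led with 15. EXMC also led at E25 with 20 of 88 cells or 22.7% (14.5 to 32.9), next to 18 CTB and 15 EVT cells. There 18 of the EXMC cells were among the 31 first-series cells and 2 among the 57 second-series cells, where CTB had 15, EPI 12 and EVT 11. Blood cells numbered 5 at E20, 6 at E22, 4 at E23, 1 at E18 and 1 at E25.

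**Figure D1:**
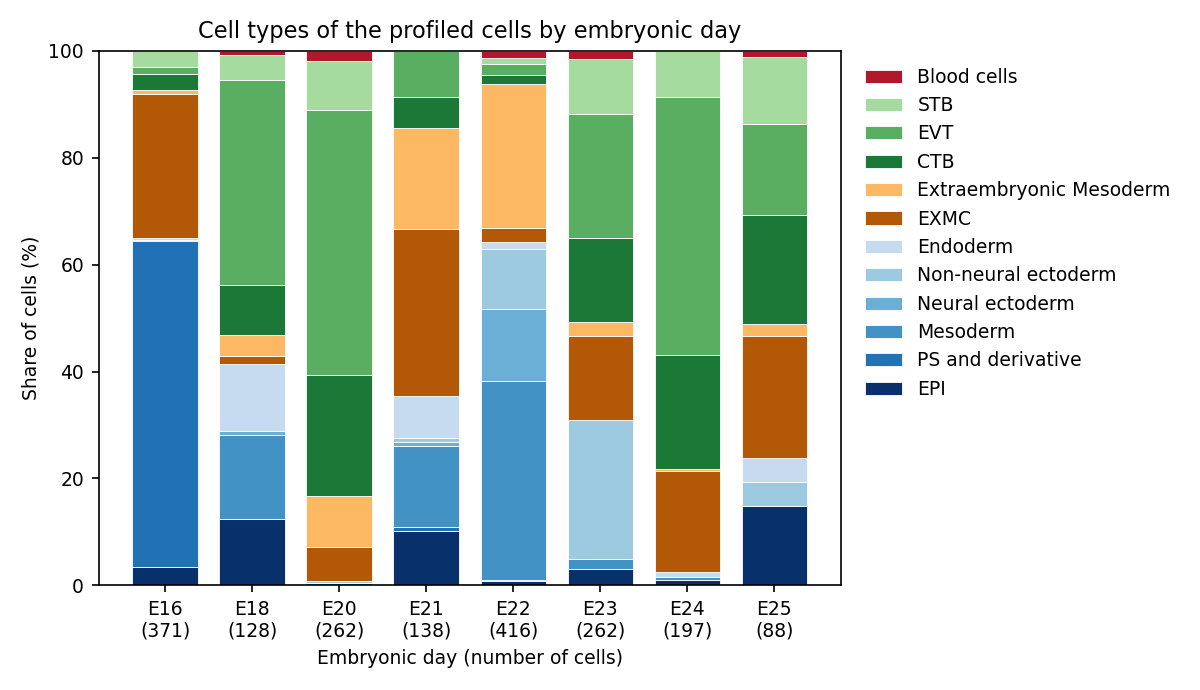
Stacked bars give the share of cells (%, y axis) of each of the 12 cell types on each embryonic day (x axis, with the number of cells in parentheses), for all cells. PS and derivative fills 60.9% of E16, the trophoblast types together fill 81.3% of E20 and 78.2% of E24, and neural ectoderm is a visible band only at E22, at 13.5%.

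RNA plates of the same day differed most at E16. The trophoblast share lay between 68.3% and 88.2% over the 6 plates of E20, between 1.54% and 7.14% over the 6 plates of E22, and between 71.9% and 85.1% over the 3 plates of E24. At E16 4 plates held 85.2% to 97.4% PS and derivative cells and at most 4.76% EXMC. The other 3 E16 plates held 15.9% to 29.6% PS and derivative and 52.1% to 66.7% EXMC. At E21 the embryonic share lay between 0% and 80% over 6 plates, and the extremes came from its smallest plates, with 13 and 10 cells. Over the 3 E21 plates with at least 20 cells it lay between 29.6% and 37.04%. The trophoblast share of the 6 plates of E23 lay between 29.8% and 67.4%.

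**Figure D2:**
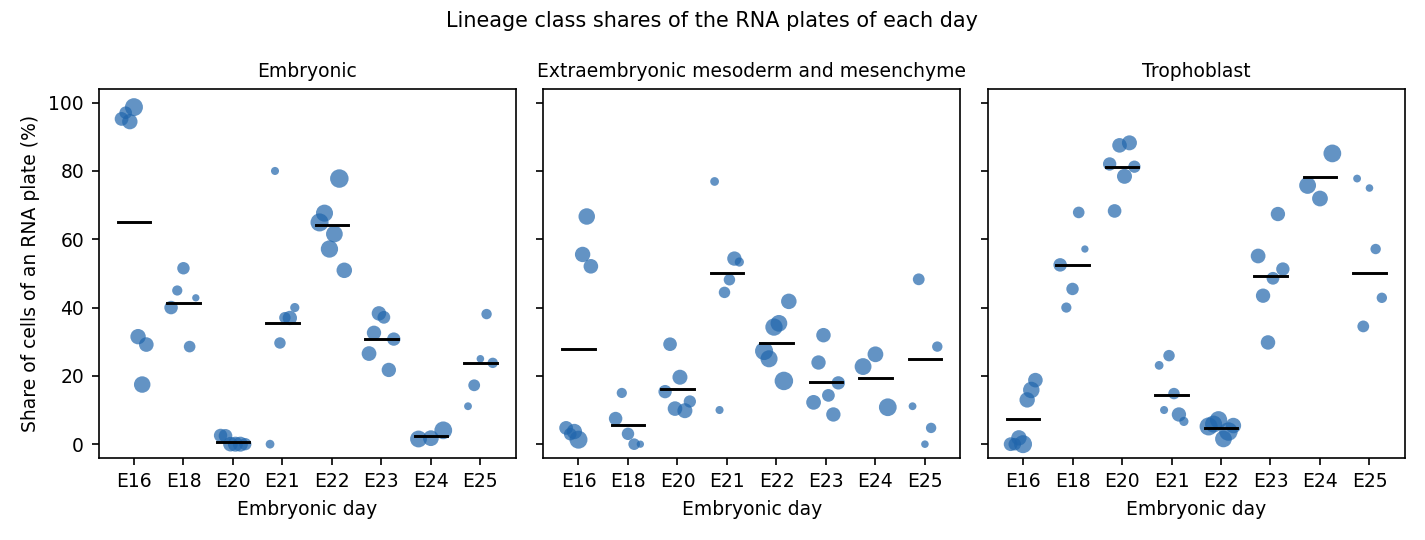
Each point is 1 RNA plate, its area growing with the number of cells, and gives the share of its cells (%, y axis) in a lineage class by embryonic day (x axis); the black bar is the share over all cells of the day. The 7 E16 plates fall apart, 4 at 94.4% to 98.7% embryonic and 3 at 17.5% to 31.5%, while the 6 E22 plates are at most 7.14% trophoblast.

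The second comparison set late days (E20 to E25) against early days (E16 and E18). PS and derivative made up 45.3% of early cells (40.9 to 49.8) and 0.147% of late cells (0.0178 to 0.529). Mesoderm stood at 4.21% early (2.62 to 6.36) and 13.4% late (11.7 to 15.4), and neural ectoderm at 0.200% early (0.00507 to 1.11) and 4.18% late (3.18 to 5.38). Non-neural ectoderm was seen in none of the 499 early cells, which allows up to 0.601%, and made up 8.88% of late cells (7.42 to 10.5). Outside the embryo proper, extraembryonic mesoderm stood at 1.60% early (0.695 to 3.13) and 12.7% late (10.97 to 14.6), CTB at 4.61% (2.94 to 6.84) and 12.8% (11.1 to 14.7), EVT at 10.8% (8.23 to 13.9) and 23.6% (21.4 to 25.97), and EXMC at 20.4% (16.99 to 24.2) and 12.4% (10.7 to 14.3). The early and late intervals of EPI, endoderm, STB and blood cells overlapped. By class, the embryonic share was 58.9% early (54.5 to 63.3) and 31.2% late (28.7 to 33.7), and the trophoblast share 18.8% (15.5 to 22.5) and 42.6% (39.9 to 45.2). Extraembryonic mesoderm and mesenchyme was at 22.04% (18.5 to 25.9) and 25.1% (22.8 to 27.5), with overlapping intervals.

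Several of these differences rested on 1 day. Without E22, the late minus early difference was -1.25 percentage points for mesoderm and -0.0948 points for neural ectoderm. Without E16, the sign turned for mesoderm, EXMC, EVT and the trophoblast class, which went from 23.7 to -9.79 points. The early cells were then all of E18 and of the second DNA series, while the late cells came from both series. These values mix day and series. Within the second series alone, EXMC was at 1.56% at E18 and at most 3.51% on a late day, at E25. Its turn to 10.8 points therefore did not hold within that series. The trophoblast class there was at 52.3% at E18, with late days between 5.05% at E22 and 98.7% at E24. Mesoderm and EVT also had late days above and below their E18 share there. Without E16, PS and derivative had no early cell, so its difference could not be negative. The sign also turned for CTB, EVT and the trophoblast class when E20 was counted as early. The embryonic class differed by -27.7 points over all cells and by -2.73 points within the second DNA series. The difference for PS and derivative was -45.1 points over all cells, -65.2 in the first series, whose early cells were all of E16, -11.2 in the second, and -12.5 without 4 E16 plates rich in this type. That for EXMC was -8.04 points, and between -11.7 and -3.25 when 1 DNA batch was left out. That for extraembryonic mesoderm was 11.1 points over all cells and 0.176 in the second series, and that for mesoderm 9.22 and 2.43. In the 9 DNA batches with at least 10 early and 10 late cells, PS and derivative had a lower late share in 6 and was absent from 3. EXMC was higher late in 4 and lower in 5. Non-neural ectoderm was seen among the late cells of 8, and with no early cell at all its late share could not be lower. Mesoderm was higher late in 4, lower in 4 and equal in 1. The trophoblast class was higher late in 7 of the 9, with differences between -14.3 and 55.4 points, and the embryonic class lower late in 7.

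Among embryonic-class cells alone, PS and derivative made up 93.8% at E16 (89.9 to 96.5). At E18 the 53 embryonic cells were 37.7% mesoderm (24.8 to 52.1) and 30.2% each of EPI and endoderm (18.3 to 44.3). At E21 the 49 embryonic cells were 42.9% mesoderm (28.8 to 57.8), 28.6% EPI (16.6 to 43.3) and 22.4% endoderm (11.8 to 36.6), with intervals that overlap those of E18. At E22 mesoderm made up 58.1% (51.9 to 64.04), neural ectoderm 20.97% (16.2 to 26.4), non-neural ectoderm 17.6% (13.2 to 22.7) and EPI 1.12% (0.232 to 3.25). At E23 the 81 embryonic cells were 83.95% non-neural ectoderm (74.1 to 91.2), 9.88% EPI (4.36 to 18.5) and 6.17% mesoderm (2.03 to 13.8). At E25 the 21 embryonic cells were 61.9% EPI (38.4 to 81.9), with 4 cells each of non-neural ectoderm and endoderm.

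Among trophoblast cells of both DNA series together, the early and late intervals overlapped for each of the 3 types. EVT made up 57.4% of the 94 early trophoblast cells (46.8 to 67.6) and 55.5% of the 580 late ones (51.4 to 59.6). CTB stood at 24.5% (16.2 to 34.4) and 30.2% (26.5 to 34.1), and STB, the fused outer layer of the placenta, at 18.1% (10.9 to 27.4) and 14.3% (11.6 to 17.4). Single days differed more. EVT was at 18.5% of the 27 trophoblast cells of E16 (6.30 to 38.1) and at 73.1% of the 67 of E18 (60.9 to 83.2). No STB was seen among the 20 trophoblast cells of E21, which allows up to 15%.

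The shares also differed between the DNA series. In the 31 RNA plates with cells in both series, extraembryonic mesoderm and mesenchyme made up 41.4% of 950 first-series cells and 8.11% of 530 second-series cells, and was lower in the second series in 31 of 31 plates. The plates were not divided in the same proportion, so second-series shares are set beside the share that an even division within each plate would give. These were 8.11% against 28.04% for the class, 5.47% against 18.5% for EXMC, 2.64% against 9.52% for extraembryonic mesoderm, 31.1% against 25% for EVT, 12.8% against 8.32% for non-neural ectoderm and 10.9% against 13.7% for CTB. A shortage of 1 class raises the shares of the others, so shares are also given with the extraembryonic mesoderm and mesenchyme cells set aside. All E18 cells were in the second series, so the E18 share of extraembryonic mesoderm and mesenchyme, 5.47% (2.23 to 10.9), has no first-series value beside it. PS and derivative at E16 was at 65.3% in the first series and 36.8% in the second, but within the divided E16 plates it was at 14.8% and 36.8%, since the plates rich in it had first-series cells only. The trophoblast class was at 72% in the first series and 93.75% in the second at E20, at 64.7% and 98.7% at E24, and at 4.73% and 5.05% at E22. With the extraembryonic mesoderm and mesenchyme class set aside, trophoblast was at 96.4% and 97.2% at E20, 95.1% and 98.7% at E24, 7.61% and 5.21% at E22, and 72.9% and 50% at E23. The embryonic class was at 56.8% and 87.9% at E22, and at 14.8% and 72% at E21, and with that class set aside at 91.4% and 90.6% at E22, and 52% of 25 cells and 81.8% of 44 at E21. At E23 it was at 18.98% and 44%, and with that class set aside at 27.1% and 46.6%. At E25 trophoblast was at 25.8% of 31 first-series cells and 63.2% of 57 second-series cells, and with that class set aside at 72.7% of 11 cells and 65.5% of 55. All 31 first-series cells came from divided E25 plates, whose 19 second-series cells were 57.9% trophoblast. The remaining second-series cells came from plates with no first-series cell.

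**Figure D3:**
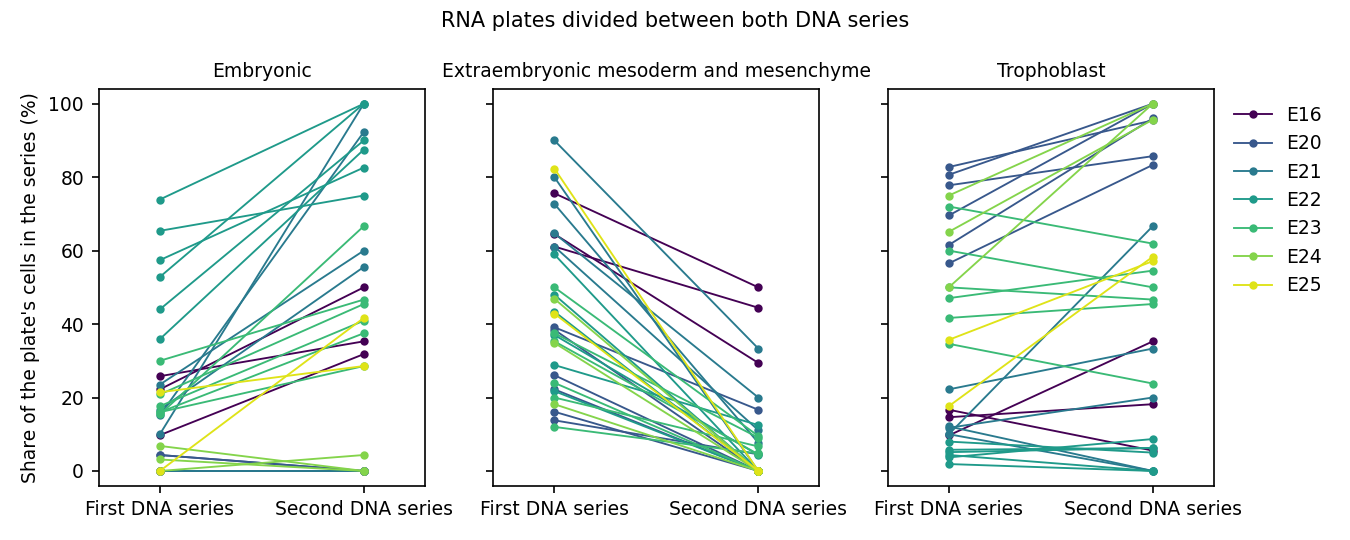
Each line joins the share (%, y axis) of a lineage class among the first-series and the second-series cells (x axis) of 1 RNA plate, coloured by embryonic day, for the 31 plates with cells in both series. The share of extraembryonic mesoderm and mesenchyme is lower in the second series in 31 of 31 plates, while the embryonic share is higher in 22 and the trophoblast share in 21, each as a share of all cells.

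The identifiers paired every RNA library with 1 DNA library, and no identifier was used more than once. In 74 of the 75 blocks of cells that shared an RNA plate and a DNA batch, DNA well numbers followed the order of the RNA well numbers. Of the 2016 DNA wells that 21 batches of 96 would hold, 92.4% had a listed cell. Batch 20 had 49 cells and well numbers up to 51, and the other batches had 71 to 96 cells. Batches 1, 2 and 3, which hold the 4 E16 plates rich in PS and derivative, had the most gaps. Below their highest well number, 25, 18 and 19 numbers had no listed cell, against at most 5 in any other batch. An RNA plate gave between 7 and 81 cells.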

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

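All tests in this part were chosen after the result had been seen. What drew attention is a signal in the library identifiers, a column that measures nothing itself: in RNA plates divided between both DNA series, extraembryonic mesoderm and mesenchyme cells made up 41.4% of first-series cells and 8.11% of second-series cells, and a random division is argued against because the lowest of 10000 shuffles within plates gave 22.3%. Position along the well numbers of the identifiers, by runs of 8, is argued against as well, since shuffles within such runs gave at least 19.4%. A division by position inside a run cannot be judged, because the shuffles mix the cells of a run. Loss of finished libraries as the whole cause is argued against, because the second series has 62 well numbers with no listed cell while the class is 105.6 cells short of its expected count. Choice of cells for the second series by cell type, or by a property that goes with it, stays open: the share was lower on 7 of 7 days, but that follows from the plates and adds no separate support. No biological explanation was tested, as both series hold cells of the same plates.

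The next pattern is the split of the E16 plates, 4 of them rich in PS and derivative and 3 rich in EXMC. Among first-series cells alone the 3 plates reached at most 22.2% PS and derivative while the 4 had at least 85.2%. That comparison cannot decide by itself, because the 3 plates held 14.8% in the first series and 36.8% in the second. The division between DNA series is argued against by the cells of both series together. Over all their cells the 3 plates reached at most 29.6%, and the 4 had at least 85.2%. The RNA identifier set is argued against because the EXMC-rich plates from the same set as the 4 others held 22.2% over all their cells. DNA library batch and kind of plate cannot be told apart, because 0 DNA batches hold E16 cells of both kinds. Different embryos or dissections also stay open and untested.

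The last pattern is the trophoblast share, high at E20 and E24 and low at E22. For E24 the RNA identifier set is argued against by the set that holds both E22 and E24. It gave 85.1% at E24 (74.96 to 92.3), with 63 of 74 cells of a single plate, and 4.81% at E22. For E20 the set cannot be judged, because all E20 cells are of a set that holds no other day. The DNA series is argued against because the lowest value of E20 or E24 within a series was 64.7% and the highest of E22 was 5.05%, and the DNA library batch because E22 had the lower share in 6 of the 6 batches with at least 10 cells of E22 and of E20 or E24. Embryonic day cannot be told apart from the embryos or dissections of that day. The other identifier set of E24 gave 73.98% (65.3 to 81.5), but other embryos or a different dissection could give the same values.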

How the results depend on the processing

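Types taken from the titles equal those of the table and test nothing. Of the other 1160 alternative values, 942 were counted as same, 11 as reversed and the rest as moved. For differences and shares, same means within the 95% interval of the reported value. Counts of batches, ranges over batches and interval bounds were judged by how close the alternative lay instead. Leaving out 1 DNA batch made up 525 of the values, with 510 same. By contrast, the first series alone left 8 of 25 differences the same and the second series alone 7 of 25. Reversed is used only for differences whose early and late intervals do not overlap. The difference of extraembryonic mesoderm and mesenchyme, 3.05 points, has overlapping intervals, so its changes of sign are not counted as reversed. Leaving out 1 DNA batch gave it -0.677 to 6.34. Both signs also came for endoderm (-2.40 to 0.0819, and -2.59 to 2.497 among embryonic cells), EPI among embryonic cells (-3.37 to 0.730) and EVT among trophoblast cells (-6.08 to 11.5), all with overlapping intervals. The weights by RNA plate, the plates left out and the single days within a DNA series were chosen after seeing the data. Leaving out E21 or E25 left each of the 25 late minus early differences within its interval. All differences here are late minus early, in percentage points. Without E16, PS and derivative gave 0.147 (0.471 among embryonic cells), mesoderm -2.20, EXMC 10.8, EVT -14.7, trophoblast -9.79, embryonic -10.2 and extraembryonic mesoderm and mesenchyme 19.6. E18 then stands alone as early, with second-series cells only, against late cells of both series. These values therefore mix day and DNA series. Within the second series, extraembryonic mesoderm and mesenchyme was at 5.47% at E18, with late days between 0% at E24 and 12% at E21. With no PS and derivative cell at E18, the difference of that type could not be negative. Without E22, mesoderm gave -1.25, neural ectoderm -0.0948, embryonic -42.2 and trophoblast 40.3. With E20 counted as early, CTB gave -0.239, EVT -6.74, trophoblast -7.01, embryonic -0.477 and extraembryonic mesoderm and mesenchyme 7.27. With E16 alone as early, which is the same as leaving out E18, embryonic gave -33.8, extraembryonic mesoderm and mesenchyme -2.67 and trophoblast 35.3. Without E20, embryonic gave -20.5 and trophoblast 14.5, and without E24 trophoblast gave 17.7. In the first DNA series alone, embryonic gave -42.7, extraembryonic mesoderm and mesenchyme 12.8 and trophoblast 29.3, and in the second -2.73, -12.5 and 13.5, with blood at 1.76. Equal weights for DNA batches gave -18.2 for embryonic and -3.95 for extraembryonic mesoderm and mesenchyme, batches with both stages alone -15.6 and -8.70. Equal weights for RNA plates gave 8.16 for the latter and 18.3 for trophoblast. Without the 4 E16 plates rich in PS and derivative, embryonic gave -1.24, extraembryonic mesoderm and mesenchyme -10.4 and trophoblast 10.8. By type, the first series gave -65.2 for PS and derivative, 13.2 for mesoderm, 5.82 for non-neural ectoderm, 17.8 for extraembryonic mesoderm and 17.4 for EVT, and the second -11.2, 2.43, 13.8, 0.176 and 4.52. EXMC gave -4.96 and -12.7, and -1.46 with equal weights for RNA plates. Without the 4 E16 plates PS and derivative gave -12.5, EXMC -21.4 and EVT 5.54. Leaving out 1 DNA batch at a time gave -32.04 to -20.6 for embryonic and 20.3 to 28.7 for trophoblast, and -11.7 to -3.25 for EXMC. Leaving out 1 RNA plate gave 51.5% to 70.1% for PS and derivative at E16 and 56.3% to 74.7% for the embryonic class. Within a single DNA series, E16 gave 65.3% PS and derivative and 69.7% embryonic in the first and 36.8% and 38.6% in the second, while the divided plates gave 14.8% and 18.5% in the first. Trophoblast gave 72% in the first and 93.75% in the second at E20, 64.7% and 98.7% at E24, and 25.8% and 63.2% at E25. At E25 the divided plates gave 57.9% trophoblast in the second. Extraembryonic mesoderm and mesenchyme gave 71.6% and 12% at E21, the embryonic class 56.8% and 87.9% at E22, and non-neural ectoderm 16.1% and 36.8% at E23. In the second series at E22, mesoderm gave 49.5% and neural ectoderm 17.2%, and in the first at E25 EPI gave 3.23%. The cause of these changes was not tested. Read depth is unknown, so what it limits was not assessed.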

Other observations

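EPI cells, by usual use the pluripotent tissue from which the embryo proper arises, were seen on 7 of the 8 days. They made up 12.5% of cells at E18 (7.32 to 19.5), 10.1% at E21 (5.66 to 16.4) and 14.8% at E25 (8.11 to 23.9), against 0.721% at E22 (0.149 to 2.09), and none was seen at E20, which allows up to 1.15%. These days differ in their mix of DNA series: E18 was all second series, E21 gave 4.55% in the first and 20% in the second, and the 3 cells of E22 were all first series. At E25 they came from 4 of 5 RNA plates, and 12 of the 13 cells were in the second DNA series. Endoderm was mostly seen at E18, with 16 cells in 5 of 5 plates, and at E21, with 11 cells in 5 of 6 plates, 8 of them in the second series. It was absent from the cells of E20 and E23, which allows up to 1.15% on each day. E20 held only 2 embryonic-class cells, so the absence of EPI and endoderm there says little about the embryonic cells of that day.

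The following shuffles were looked at after the division between DNA series had been seen. They leave out extraembryonic mesoderm and mesenchyme cells, since their shortage in the second series raises every other share. Of the remaining 487 second-series cells in the divided plates, CTB made up 11.9%, below the lowest of 10000 shuffles within plates at 13.96% and within runs of 8 wells at 12.9%. No other type lay outside the full range of the shuffles, from the lowest to the highest. Some did lie outside the central 95% of the shuffles. Mesoderm was at 13.6%, between 9.65% and 16.4% within plates, and EVT at 33.9%, between 28.3% and 37.6%. Non-neural ectoderm was at 13.96%, below the highest shuffle within plates at 14.4%, and STB at 10.7%, below the highest at 12.1%. The central 95% ended at 13.1% for non-neural ectoderm, within plates and within runs. For STB it ended at 10.5% within plates and 11.3% within runs. Blood cells were at 2.46%, above its end at 2.26% in both. The embryonic class was at 41.1%, above its end at 40.2% within plates and 40.9% within runs. The trophoblast class was at 56.5%, below its start at 58.3% and 57.5%. The shortage of CTB, which is part of the trophoblast class, in turn raises the shares of the other types.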
